A study of Homo sapiens with 76 samples.

How the data were processed

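RNA of NOMO-1 cells was measured in 75 libraries, each of which has a column in a deposited table, and groups were taken from the sample labels alone. Of the 76 labelled samples, guide 1 replicate 2 of the second PTPN23 experiment was not analysed here. For 1 sample the labels disagree on the day: guide 2 replicate 2 of triple-knockout cells is called day 6 in its title and day 12 in its time entry, and the title was followed. Per the labels' protocols, cells were infected with sgRNA vectors, total RNA was extracted with TRIzol and libraries were made with a TruSeq kit (v2). The deposited values are raw read counts per gene: per the submitters' processing notes, reads were aligned to hg38 with HISAT2 2.1.0 and counted with HTSeq 0.13.5. The gene annotation, the strand setting and the filter on low counts are not given in the sources used here.

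The tables of the second PTPN23 experiment and of UBAP1, HGS, USP8, TSG101 and CLTC hold 11436, 11078, 11457, 10096, 11118 and 10645 genes, all with at least 10 counts in every library. In tables without this limit, genes with a mean of at least 10 that lie below 10 in some library numbered 582 of 11609 (first PTPN23 experiment) and 2326 of 15624, 2489 of 15765 and 1034 of 15301 (triple-knockout days 6, 12 and 18). Of the 62754 Ensembl identifiers of the triple-knockout libraries, 62700 were given symbols from GENCODE 29, and outdated symbols in the other tables were replaced by current ones. No 2 libraries were identical.

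Each comparison was fitted on counts with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr by group, and a robust quasi-likelihood test of the mean of both guides against the sgNEG group of the same experiment. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. Differences between effects were tested as contrasts in a joint fit of both experiments, each with its own sgNEG libraries. In this contrast cell type or knockout and experiment cannot be separated. Standard errors were computed from the log2 fold change and the F statistic, and medians of lists are given on the log2 scale. Where an arm holds 1 library, it was assumed to vary like the other groups.

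Gene sets were tested with camera (limma 3.58.1), with a preset correlation between genes of 0.01, and adjusted over all lists with at least 3 genes tested. The 35 lists (714 genes) were written from general knowledge before the data were examined, as were the comparisons, the tests and most of the alternatives. Beside each count of changed genes in a list the count adjusted over the list alone is given. The genes named per comparison followed a fixed rule: the target; the 5 largest rises and falls among called genes with a mean log2 CPM of at least 3 and the same direction with both guides; the list members with the smallest adjusted p; the 6 shared genes per direction whose smallest change was largest; and the 5 largest differences per direction. From lists, members that lost their call without a single library were passed over where others were at hand. Results for some withheld items are not reported here.

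The alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, each guide alone, the replicate number as a block, each library left out, camera with an estimated correlation, fry, an adjusted p below 0.01, a mean log2 CPM of at least 4 for correlations, and each wild-type PTPN23 experiment alone. Fits with a library type term and without single libraries in doubt were added after the library types were seen. Replicate numbers were taken to pair libraries where every same-number correlation of deviations from the group means was over 0.1 with 3 numbers. This held in the second PTPN23 experiment (0.13 to 0.51), UBAP1 (0.14 to 0.74) and CLTC (0.16 to 0.66), a hint from the data since the labels do not define the numbers.

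The fits were tested on simulated data made from the sgNEG levels and the measured spread. Of genes simulated with a 2-fold change edgeR recovered 72% in the first PTPN23 experiment, 98% in the second, 100% for UBAP1 and HGS, 82% for USP8, 98% for TSG101 and 80% for CLTC, and 34%, 0% and 82% for triple-knockout days 6, 12 and 18. Calls of edgeR at 1.25-fold reached at most 52% (HGS), so small changes stay below what these libraries resolve. Of simulated edgeR calls 7.1% were false in the first PTPN23 experiment, 4.4% in the second, 3.2% for UBAP1, 7.7% for HGS, 5.6% for USP8, 5.8% for TSG101, 9.8% for CLTC and 8.2% and 9.2% on triple-knockout days 6 and 18. On day 12 the only call was false. DESeq2 reached 12.4% for USP8, 16.5% for CLTC, 28.4% on day 6 and 84.9% on day 12. Of differences, edgeR had most false calls for CLTC against PTPN23 (9.9%; DESeq2 17.6%), and DESeq2 for day 18 against day 6 (40%). Camera recovered both lists simulated at 1.25-fold except on triple-knockout day 12 and for day 18 against day 6, and called 1 unchanged list in the first PTPN23 experiment and 1 between both PTPN23 experiments. With an estimated correlation it recovered neither list in the first PTPN23 experiment, UBAP1, the triple-knockout days and day 18 against day 6. A lost call there says little about a change of the list. In the other comparisons it recovered both lists. The simulated genes varied independently, so neither correlation setting was tested on genes that move together. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.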

Results

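Gene expression was measured by RNA sequencing in NOMO-1, an acute myeloid leukaemia line of monocytic type, after infection with vectors carrying sgRNAs. The targets were PTPN23, UBAP1, HGS, USP8 and TSG101, whose products belong to or act with the ESCRT machinery that sorts ubiquitinated membrane proteins at endosomes, and CLTC, the clathrin heavy chain of endocytic coats. Every experiment used 2 guides per target and its own libraries with a non-targeting guide (sgNEG), and PTPN23 was targeted in 2 separate experiments. PTPN23 was also targeted in cells lacking CASP8 (a caspase of death receptor signalling), RIPK3 (a kinase of necroptosis) and GSDMD (the pore protein of pyroptosis), called triple-knockout cells here and sampled on days 6, 12 and 18. All other cells were sampled on day 6.

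The sgNEG, guide 1 and guide 2 groups held 3 libraries each in the HGS, USP8, TSG101 and CLTC experiments, 3, 3 and 2 in the UBAP1 experiment, and 2 each in the first PTPN23 experiment. In the second PTPN23 experiment they held 3, 2 and 3, because guide 1 replicate 2 was not analysed here. The triple-knockout groups held 2 libraries each on days 6 and 18, and 1, 2 and 2 on day 12. The labels number the replicates but do not describe separate cultures, so the p-values measure the spread between these libraries, which may be technical.

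Total counts per library ran from 5.19 to 7.01 M in the first PTPN23 experiment, 6.74 to 8.88 M in the second, 4.42 to 7.84 M for UBAP1, 7.04 to 9.73 M for HGS, 2.3 to 9.58 M for USP8, 6.16 to 8.89 M for TSG101 and 3.26 to 8.32 M for CLTC. The triple-knockout libraries held 9.82 to 18.53 M on day 6, 8.42 to 20.38 M on day 12 and 8.42 to 9.87 M on day 18. The tables of the second PTPN23 experiment and of UBAP1, HGS, USP8, TSG101 and CLTC hold only genes with at least 10 counts in every library. Genes silenced by a knockout, and genes silent with sgNEG and switched on by it, are therefore missing from these tables and from the counts of fallen and risen genes below. The largest rises and falls named below are those of called genes with a mean log2 CPM of at least 3 (CPM, counts scaled to library size) that moved the same way with both guides.

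On hg38, PTPN23 lies on chromosome 3 (47381011 to 47413441), UBAP1 on chromosome 9 (34179005 to 34252523), HGS on chromosome 17 (81683326 to 81703138), USP8 on chromosome 15 (50424380 to 50514419), TSG101 on chromosome 11 (18468336 to 18527232) and CLTC on chromosome 17 (59619689 to 59696956). CASP8 lies on chromosome 2 (201233443 to 201287711), RIPK3 on chromosome 14 (24336021 to 24340045) and GSDMD on chromosome 8 (143553207 to 143563062). All are protein-coding genes. Guide RNAs act on DNA, so the level of the target RNA does not measure how many cells lost the protein.

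In order to investigate the response to loss of PTPN23, 4 guide libraries were compared with 2 sgNEG libraries in the first experiment. PTPN23, an ESCRT adaptor of the BRO1 family, was at 73.8 and 72.8 CPM with sgNEG, 47.4 and 43 with guide 1 and 40.7 and 53.3 with guide 2 (log2 fold change −0.67 ± 0.14 SE, adjusted p = 0.09). LIPG, endothelial lipase, rose most (3.16 ± 0.26, edgeR adjusted p = 0.0096). It was followed by HEG1, a transmembrane protein of cell junctions (2.16 ± 0.30, adjusted p = 0.044), SLAMF7, an immune cell receptor (1.80 ± 0.22, adjusted p = 0.033), LGMN, a lysosomal protease (1.72 ± 0.22, adjusted p = 0.039), and PRDM1, a transcriptional repressor (1.72 ± 0.23, adjusted p = 0.039). BIRC3, an inhibitor of apoptosis induced by NF-kB, rose by 1.51 ± 0.16 and the chemokine gene CXCL8 by 1.03 ± 0.15. The sterol genes INSIG1 (1.41 ± 0.17) and HMGCS1 (1.17 ± 0.14), the autophagy receptor gene SQSTM1 (1.27 ± 0.19), the growth arrest gene BTG2 (1.14 ± 0.17) and the glycolysis regulator PFKFB3 (1.05 ± 0.16) also rose. In all, 29 of 11827 genes rose and none fell.

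By list, NF-kB and TNF response genes rose as a group in this first experiment (2 of 36 changed, 21 adjusted over the list alone; median log2 fold change 0.87; camera adjusted p = 1.3e-16, but adjusted p = 0.501 with an estimated correlation). Sterol genes rose (2 of 23, 14 adjusted over the list alone; adjusted p = 1.04e-12, and adjusted p = 0.501 with an estimated correlation). So did lysosome and autophagy genes (1 of 30, 7 adjusted over the list alone; adjusted p = 1.54e-08, and adjusted p = 0.501 with an estimated correlation). Immediate early genes rose too (1 of 21, 6 adjusted over the list alone; adjusted p = 0.00442, and adjusted p = 0.633 with an estimated correlation). Death receptor genes passed the same test narrowly (0 of 13, 5 adjusted over the list alone; adjusted p = 0.0464, and adjusted p = 0.633 with an estimated correlation), TNFRSF10D being at 0.80 ± 0.15 (adjusted p = 0.073). The apoptosis (adjusted p = 0.109), pyroptosis (adjusted p = 0.117) and necroptosis (adjusted p = 0.26) lists did not pass. These calls rest on few libraries: none of the genes named above passed without sgNEG replicate 1 (LIPG adjusted p = 0.504) or without sgNEG replicate 2 (LIPG adjusted p = 0.108). Fold changes of LIPG (3.19 and 3.13) and INSIG1 (1.43 and 1.38) stayed near the main ones. Others moved more, HEG1 to 1.83 and 2.62 and LGMN to 1.49 and 1.99. With 1 sgNEG library left hardly any gene passed at all. The count was 8 and 92 without guide 1 replicates 1 and 2 and 307 and 68 without guide 2 replicates 1 and 2. HEG1, LGMN, PRDM1, CXCL8, BTG2 and PFKFB3 also lost their call without guide 1 replicate 1 (adjusted p from 0.0561 to 0.067). DESeq2 called 310 genes, edgeR without its expression filter 356, and guide 1 and guide 2 alone 1 and 2 genes. With either guide alone every gene named above but LIPG lost its call (adjusted p from 0.053 to 0.117).

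The second PTPN23 experiment compared 5 guide libraries with 3 sgNEG libraries. PTPN23 fell from 59.6, 82.2 and 81.9 CPM with sgNEG to 41.3 and 43.4 with guide 1 and 42.3, 44.1 and 41.8 with guide 2 (−0.81 ± 0.10, edgeR adjusted p = 1.7e-05). The largest rises were LIPG (2.86 ± 0.18, adjusted p = 7.8e-09), CEMIP, a hyaluronan-binding protein (2.59 ± 0.13, adjusted p = 4.6e-10), MET, the hepatocyte growth factor receptor (2.57 ± 0.21, adjusted p = 9.3e-08), SNAI1, a transcription factor of epithelial-mesenchymal transition (2.51 ± 0.17, adjusted p = 1.2e-08), and ATF3, a stress-induced transcription factor (2.46 ± 0.16, adjusted p = 1.2e-08). The largest falls were SEPTIN1, a septin GTPase (−1.07 ± 0.14, adjusted p = 2.4e-05), ZNF593, a zinc finger protein (−0.94 ± 0.14, adjusted p = 8e-05), VAT1L (−0.91 ± 0.11, adjusted p = 8.5e-06), the mitochondrial ribosomal protein gene MRPL23 (−0.89 ± 0.16, adjusted p = 0.00044) and UPB1, an enzyme of pyrimidine breakdown (−0.86 ± 0.12, adjusted p = 3.8e-05). edgeR called 3511 of 11436 genes (1884 higher, 1627 lower), DESeq2 3197, and guide 1 alone, with only 2 libraries, 1231.

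Inflammatory genes rose broadly: 32 of 35 NF-kB and TNF response genes rose (33 adjusted over the list alone; camera adjusted p = 8.13e-15, adjusted p = 0.0736 with an estimated correlation). Among them were CXCL8 (1.34 ± 0.10), IL1B (1.17 ± 0.10), the dendritic cell marker CD83 (0.98 ± 0.10) and the adhesion molecule ICAM1 (0.89 ± 0.09). Of 29 lysosome and autophagy genes 20 rose (22 adjusted over the list alone; adjusted p = 5.11e-10, adjusted p = 0.105 with an estimated correlation), with the cathepsin gene CTSB at 1.48 ± 0.09 and GPNMB, a target of MITF-family factors, at 1.77 ± 0.11. Ferroptosis and NRF2 target genes rose (11 of 18, 12 adjusted over the list alone; adjusted p = 3.97e-05, adjusted p = 0.0736 with an estimated correlation), led by the glutathione synthesis gene GCLC (1.28 ± 0.10), the cystine transporter gene SLC7A11 (1.48 ± 0.12) and HMOX1, heme oxygenase (1.10 ± 0.10). TGF-beta targets rose (9 of 11, 10 adjusted over the list alone; adjusted p = 1.65e-07, adjusted p = 0.0736 with an estimated correlation). So did immediate early genes (13 of 21, 13 adjusted over the list alone; adjusted p = 0.000737, adjusted p = 0.231 with an estimated correlation) such as the MAP kinase phosphatase gene DUSP1 (2.46 ± 0.12) and JUN (1.02 ± 0.09). Genes of MYC targets and ribosome biogenesis fell (17 of 20, 18 adjusted over the list alone; adjusted p = 1.45e-07, adjusted p = 0.0736 with an estimated correlation). RRP12 was among them (−0.75 ± 0.09). Cell cycle genes fell (15 of 30, 16 adjusted over the list alone; adjusted p = 0.000223, adjusted p = 0.231 with an estimated correlation). PLK1 was among them (−0.45 ± 0.09).

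Among death genes in this experiment, BMF, a proapoptotic BH3-only protein (1.22 ± 0.09), CFLAR, an inhibitor of CASP8 (0.71 ± 0.09), CYLD, a deubiquitinase of RIPK1 signalling (0.68 ± 0.08), IL18 (0.48 ± 0.11) and the TNF receptor genes TNFRSF21 (0.79 ± 0.10) and TNFRSF1B (0.60 ± 0.09) rose. MLKL, the effector of necroptosis (−0.40 ± 0.10), and PYCARD, the inflammasome adaptor (−0.57 ± 0.11), fell. With guide 1 alone IL18 (0.39, adjusted p = 0.0594) and MLKL (−0.37, adjusted p = 0.0746) lost their call. As lists, death receptors (adjusted p = 0.0893), apoptosis (adjusted p = 0.151), pyroptosis (adjusted p = 0.151) and necroptosis (adjusted p = 0.827) did not pass. In the comparison of both PTPN23 experiments edgeR found 0 of 11321 genes with a different response (429 at unadjusted p under 0.05, DESeq2 3). In simulated data it recovered 24% of 1.5-fold and 56% of 2-fold differences here, so many differences of this size would be missed. As lists, 6 differed. Sterol genes responded less in the second experiment (0 of 23, 2 adjusted over the list alone; median difference −0.43, adjusted p = 3.32e-12, adjusted p = 0.325 with an estimated correlation) and TGF-beta targets more (0.37, adjusted p = 0.000351, adjusted p = 0.234 with an estimated correlation).

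**Figure D1:**
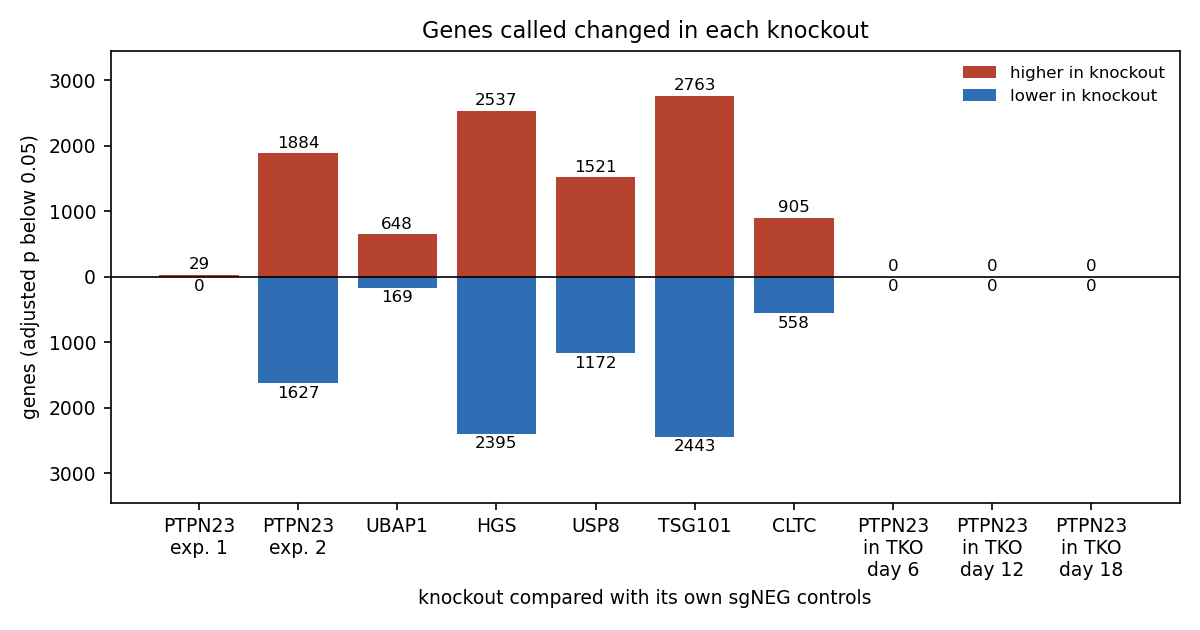
Genes that rose or fell in each knockout against its own sgNEG libraries (edgeR, adjusted p below 0.05).

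UBAP1, a subunit of the ESCRT-I complex, was compared in 5 guide libraries and 3 sgNEG libraries. Its own RNA was not called changed and gives no check of the labels: sgNEG libraries were at 96.9, 110 and 92.3 CPM, those labelled guide 1 at 85.8, 88.5 and 83.4 and those labelled guide 2 at 128 and 126 (0.06 ± 0.10, adjusted p = 0.74; guide 1 −0.22, guide 2 0.34). The largest rises were ATF3 (2.67 ± 0.17, edgeR adjusted p = 8.2e-06), the procollagen protease gene ADAMTS2 (2.45 ± 0.21, adjusted p = 3.6e-05), SNAI1 (2.38 ± 0.16, adjusted p = 8.2e-06), DUSP1 (2.38 ± 0.17, adjusted p = 1.5e-05) and ATP6V0D2, a subunit of the vacuolar proton pump (2.36 ± 0.18, adjusted p = 1.8e-05). The largest falls were ART3, an ADP-ribosyltransferase family member (−1.18 ± 0.16, adjusted p = 0.00052), CPNE7, a copine (−1.11 ± 0.22, adjusted p = 0.0068), RHPN1 (−0.98 ± 0.17, adjusted p = 0.003), SAP25 (−0.96 ± 0.24, adjusted p = 0.028) and IL22RA2, a soluble IL-22 receptor (−0.92 ± 0.13, adjusted p = 0.00095).

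NF-kB and TNF response genes rose in the UBAP1 knockout (21 of 34, 28 adjusted over the list alone; camera adjusted p = 7.01e-19, adjusted p = 0.0181 with an estimated correlation), with CXCL8 at 1.30 ± 0.13, IL1B at 0.97 ± 0.10 and the ubiquitin-editing inhibitor TNFAIP3 at 0.92 ± 0.11. Lysosome and autophagy genes (17 of 30, 24 adjusted over the list alone; adjusted p = 1.08e-14), ferroptosis and NRF2 targets (9 of 18, 14 adjusted over the list alone; adjusted p = 3.96e-09) and TGF-beta targets (6 of 11, 8 adjusted over the list alone; adjusted p = 1.8e-08) rose. Among them were GPNMB (2.18 ± 0.19), SLC7A11 (1.55 ± 0.15) and BAMBI, a decoy TGF-beta receptor (1.16 ± 0.14). MYC targets fell (4 of 20, 13 adjusted over the list alone; adjusted p = 1.2e-06). RRP12 was among them (−0.58 ± 0.11). Of the death lists only death receptors passed (2 of 11, 2 adjusted over the list alone; adjusted p = 0.0315, adjusted p = 0.401 with an estimated correlation), while apoptosis (adjusted p = 0.211), pyroptosis (adjusted p = 0.218) and necroptosis (adjusted p = 0.394) did not. BMF (0.83 ± 0.11), CFLAR (0.59 ± 0.09) and NINJ1, which ruptures the membrane of dying cells (0.62 ± 0.12), rose. In all 817 of 11078 genes changed (648 higher, 169 lower), 2689 with a replicate block and 367 with guide 2 alone. With guide 2 alone CPNE7 (−1.05, adjusted p = 0.0647), NINJ1 (0.54, adjusted p = 0.0645), RRP12 (−0.51, adjusted p = 0.0722) and SAP25 (−1.21, adjusted p = 0.0591; guide 1 alone −0.72, adjusted p = 0.147) lost their call. The count was 2860 without sgNEG replicate 1, 383 without sgNEG replicate 3, 541 without guide 1 replicate 2 and 428 and 476 without guide 2 replicates 1 and 2. SAP25 lost its call without sgNEG replicate 2 or 3, guide 1 replicate 2 or either guide 2 library (adjusted p from 0.0564 to 0.138).

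HGS, the ESCRT-0 subunit that binds ubiquitinated cargo, was compared in 6 guide libraries and 3 sgNEG libraries. HGS fell from 148, 131 and 132 CPM to 112, 110 and 114 with guide 1 and 83.8, 82.1 and 89.3 with guide 2 (−0.49 ± 0.06, edgeR adjusted p = 1e-06). ATP6V0D2 (3.32 ± 0.22, adjusted p = 3.9e-10), the neutrophil chemokine gene CXCL5 (2.89 ± 0.21, adjusted p = 8.3e-10), S100B, a calcium-binding protein (2.60 ± 0.16, adjusted p = 3.2e-11), the apolipoprotein gene APOE (2.57 ± 0.14, adjusted p = 8.4e-12) and ADAMTS2 (2.51 ± 0.12, adjusted p = 9.8e-13) rose most. PRLR, the prolactin receptor (−1.51 ± 0.09, adjusted p = 1e-10), ART3 (−1.42 ± 0.09, adjusted p = 8.4e-11), VAT1L (−1.34 ± 0.09, adjusted p = 2.2e-10), the granzyme gene GZMA (−1.32 ± 0.14, adjusted p = 1.1e-07) and UPB1 (−1.19 ± 0.10, adjusted p = 5.3e-09) fell most. In all 4932 of 11457 genes changed (2537 higher, 2395 lower).

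In the HGS knockout 31 of 35 NF-kB and TNF response genes rose (32 adjusted over the list alone; camera adjusted p = 2.17e-14, adjusted p = 0.00278 with an estimated correlation). Among them were PTX3, a secreted pattern recognition molecule (1.37 ± 0.08), IL1B (0.99 ± 0.06) and ICAM1 (1.01 ± 0.07). Lysosome and autophagy genes rose (28 of 30, 28 adjusted over the list alone; adjusted p = 5.98e-14, adjusted p = 0.00701 with an estimated correlation), with CTSB at 1.60 ± 0.07 and the cathepsin gene CTSD at 1.24 ± 0.07, as did ferroptosis and NRF2 targets (15 of 19, 15 adjusted over the list alone; adjusted p = 7.65e-06), with HMOX1 at 1.42 ± 0.07. Interferon-stimulated genes rose (12 of 26, 12 adjusted over the list alone; adjusted p = 0.0131, adjusted p = 0.0956 with an estimated correlation). STAT2 was among them (0.64 ± 0.07). Antigen presentation genes rose as well (6 of 13, 7 adjusted over the list alone; adjusted p = 0.0124, adjusted p = 0.305 with an estimated correlation). The costimulatory gene CD86 was among them (0.81 ± 0.06). Monocyte maturation genes rose too (19 of 28, 19 adjusted over the list alone; adjusted p = 2.24e-05, adjusted p = 0.0727 with an estimated correlation). MMP9 (1.53 ± 0.07) and CD14 (1.22 ± 0.08) were among them. Heat shock genes fell (8 of 10, 8 adjusted over the list alone; adjusted p = 0.00791, adjusted p = 0.204 with an estimated correlation). The chaperone gene HSPD1 was among them (−0.57 ± 0.06). All 20 MYC targets fell (20 adjusted over the list alone; adjusted p = 3.69e-12, adjusted p = 0.0237 with an estimated correlation). Death receptors (6 of 12 rose, 6 adjusted over the list alone; adjusted p = 0.035, adjusted p = 0.325 with an estimated correlation) and pyroptosis (8 of 14 rose, 8 adjusted over the list alone; adjusted p = 0.0434, adjusted p = 0.188 with an estimated correlation) passed. So did necroptosis (4 of 10 rose, 6 adjusted over the list alone; adjusted p = 0.0404, adjusted p = 0.188 with an estimated correlation), and apoptosis did not (adjusted p = 0.226). TNFRSF21 (1.15 ± 0.09), IL18 (0.71 ± 0.10), NINJ1 (0.66 ± 0.06), CYLD (0.60 ± 0.06) and BMF (1.44 ± 0.07) rose.

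USP8, a deubiquitinase that acts on endosomal cargo, was compared in 6 guide libraries and 3 sgNEG libraries. Its RNA was at 40.4, 32.4 and 40.8 CPM with sgNEG, at 16.4, 24.1 and 30.3 in libraries labelled guide 1 and at 46.3, 40.1 and 19 in those labelled guide 2 (−0.40 ± 0.26, adjusted p = 0.28), which gives no check of the labels. HES1, a repressor downstream of Notch (4.29 ± 0.36, edgeR adjusted p = 5.6e-05), ATP6V0D2 (4.01 ± 0.42, adjusted p = 0.00017), APOE (3.88 ± 0.37, adjusted p = 0.00011), the decoy receptor gene IL1R2 (3.82 ± 0.37, adjusted p = 0.00012) and ATF3 (3.77 ± 0.14, adjusted p = 4.3e-07) rose most. HHLA2, a B7-family ligand (−1.76 ± 0.15, adjusted p = 5.6e-05), IL18RAP, a subunit of the IL-18 receptor (−1.59 ± 0.28, adjusted p = 0.0027), GJB6, a connexin (−1.52 ± 0.24, adjusted p = 0.0017), F13A1, coagulation factor XIII (−1.52 ± 0.34, adjusted p = 0.0095), and BMX, a Tec-family kinase (−1.51 ± 0.23, adjusted p = 0.0012), fell most. In all 2693 of 10096 genes changed (1521 higher, 1172 lower).

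In the USP8 knockout NF-kB and TNF response genes rose (26 of 34, 29 adjusted over the list alone; camera adjusted p = 7.23e-15, adjusted p = 0.149 with an estimated correlation), with ICAM1 and CD83 both at 1.70 ± 0.13 and SOD2, mitochondrial superoxide dismutase, at 2.05 ± 0.23. Lysosome and autophagy genes rose (23 of 30, 24 adjusted over the list alone; adjusted p = 1.31e-12, adjusted p = 0.149 with an estimated correlation). The same held for immediate early genes (11 of 19, 12 adjusted over the list alone; adjusted p = 4.04e-06, adjusted p = 0.149 with an estimated correlation) and ferroptosis and NRF2 targets (12 of 18, 13 adjusted over the list alone; adjusted p = 3.62e-06, adjusted p = 0.39 with an estimated correlation). Among them were GPNMB (3.33 ± 0.22), DUSP1 (3.72 ± 0.27) and HMOX1 (1.99 ± 0.23). Cell cycle genes fell (21 of 30, 26 adjusted over the list alone; adjusted p = 9.03e-10, adjusted p = 0.149 with an estimated correlation). CCNA2 was among them (−0.72 ± 0.10). MYC targets fell as well (15 of 20, 16 adjusted over the list alone; adjusted p = 1.16e-07, adjusted p = 0.149 with an estimated correlation). POLR1B was among them (−1.23 ± 0.16). Death receptors passed (5 of 12 rose, 5 adjusted over the list alone; adjusted p = 0.0485, adjusted p = 0.39 with an estimated correlation), whereas apoptosis (adjusted p = 0.135), pyroptosis (adjusted p = 0.248) and necroptosis (adjusted p = 0.155) did not. TNFRSF9 (2.58 ± 0.32), BMF (1.59 ± 0.19), CFLAR (1.09 ± 0.15), the BH3-only genes PMAIP1 (1.11 ± 0.16) and BBC3 (1.08 ± 0.16), GSDME (1.22 ± 0.20) and CYLD (0.96 ± 0.15) rose, and MLKL fell (−0.87 ± 0.14). The count was 1767, 1782 and 1628 without sgNEG replicates 1, 2 and 3.

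TSG101, a subunit of the ESCRT-I complex that binds ubiquitin, was compared in 6 guide libraries and 3 sgNEG libraries. TSG101 fell from 58.4, 57.1 and 60.8 CPM to 25, 30.4 and 26.8 with guide 1 and 25.4, 29.9 and 27.8 with guide 2 (−1.09 ± 0.09, edgeR adjusted p = 6.3e-08). HES1 (4.76 ± 0.28, adjusted p = 6e-09), DUSP1 (4.48 ± 0.15, adjusted p = 5.6e-12), SNAI1 (4.28 ± 0.20, adjusted p = 1.5e-10), ATF3 (4.25 ± 0.16, adjusted p = 5.6e-12) and ATP6V0D2 (4.16 ± 0.19, adjusted p = 5e-11) rose most. GJB6 (−2.39 ± 0.17, adjusted p = 3.9e-09), VAT1L (−1.92 ± 0.14, adjusted p = 5.8e-09), ART3 (−1.89 ± 0.13, adjusted p = 2.5e-09), the Wnt inhibitor gene APCDD1 (−1.75 ± 0.10, adjusted p = 7.5e-10) and F13A1 (−1.73 ± 0.14, adjusted p = 9.1e-08) fell most. In all 5206 of 11118 genes changed (2763 higher, 2443 lower).

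In the TSG101 knockout 34 of 35 NF-kB and TNF response genes rose (35 adjusted over the list alone; camera adjusted p = 6.05e-17, adjusted p = 0.116 with an estimated correlation), with CXCL8 at 2.63 ± 0.12, CD83 at 1.98 ± 0.12 and the signalling adaptor gene TRAF1 at 1.86 ± 0.12. TGF-beta targets rose (10 of 11, 10 adjusted over the list alone; adjusted p = 2.34e-07, adjusted p = 0.0188 with an estimated correlation). ID3 was among them (2.96 ± 0.16). Lysosome and autophagy genes rose (29 of 31, 29 adjusted over the list alone; adjusted p = 9.7e-13, adjusted p = 0.116 with an estimated correlation). The same held for ferroptosis and NRF2 targets (16 of 18, 16 adjusted over the list alone; adjusted p = 6.1e-09, adjusted p = 0.116 with an estimated correlation) and immediate early genes (17 of 22, 18 adjusted over the list alone; adjusted p = 1.07e-07, adjusted p = 0.276 with an estimated correlation). Among them were GPNMB (2.72 ± 0.13), SLC7A11 (2.72 ± 0.13) and EGR2 (3.12 ± 0.15). MYC targets fell (18 of 20, 18 adjusted over the list alone; adjusted p = 5.37e-08, adjusted p = 0.0188 with an estimated correlation). So did granulocyte and progenitor genes (7 of 10, 7 adjusted over the list alone; adjusted p = 0.000458, adjusted p = 0.177 with an estimated correlation) such as FLT3 (−1.27 ± 0.12) and the granule protein genes CTSG (−1.04 ± 0.10) and MPO (−1.05 ± 0.11). Death receptors passed (7 of 13 rose, 7 adjusted over the list alone; adjusted p = 0.0167, adjusted p = 0.349 with an estimated correlation), while apoptosis (adjusted p = 0.135), pyroptosis (adjusted p = 0.373) and necroptosis (adjusted p = 0.373) did not. PMAIP1 (1.78 ± 0.13), BMF (1.65 ± 0.11), CFLAR (1.31 ± 0.09), TNFRSF21 (1.13 ± 0.11), IL18 (1.06 ± 0.12), CYLD (1.07 ± 0.09) and TICAM1, an adaptor of Toll-like receptors (1.06 ± 0.11), rose, and MLKL fell (−0.98 ± 0.12).

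CLTC was compared in 6 guide libraries and 3 sgNEG libraries. CLTC fell from 385, 432 and 366 CPM to 180, 214 and 159 with guide 1 and 132, 198 and 166 with guide 2 (−1.17 ± 0.16, edgeR adjusted p = 0.00046). HTRA1, a secreted serine protease (3.80 ± 0.53, adjusted p = 0.00053), the stress cytokine gene GDF15 (3.53 ± 0.30, adjusted p = 5.1e-05), MSR1, a scavenger receptor of macrophages (3.39 ± 0.38, adjusted p = 0.00012), CADM1, an adhesion molecule (3.06 ± 0.49, adjusted p = 0.0013), and CLDN1, a claudin (2.96 ± 0.32, adjusted p = 0.00012), rose most. MPO, myeloperoxidase (−2.34 ± 0.24, adjusted p = 9.2e-05), HHLA2 (−2.07 ± 0.21, adjusted p = 9e-05), IL18RAP (−1.97 ± 0.22, adjusted p = 0.00012), PRLR (−1.95 ± 0.38, adjusted p = 0.0047; guide 2 alone −1.16, adjusted p = 0.225) and APCDD1 (−1.94 ± 0.16, adjusted p = 5.1e-05) fell most. In all 1463 of 10645 genes changed (905 higher, 558 lower), 2911 with a replicate block and 351 with guide 2 alone.

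In the CLTC knockout NF-kB and TNF response genes rose (20 of 34, 25 adjusted over the list alone; camera adjusted p = 6.05e-11, adjusted p = 0.087 with an estimated correlation), with CD83 at 1.16 ± 0.15 and the urokinase gene PLAU at 1.01 ± 0.15. Lysosome and autophagy genes rose (16 of 29, 21 adjusted over the list alone; adjusted p = 2.29e-13, adjusted p = 0.0725 with an estimated correlation). The same held for TGF-beta targets (10 of 11, 10 adjusted over the list alone; adjusted p = 7.18e-09, adjusted p = 0.103 with an estimated correlation) and monocyte maturation genes (12 of 27, 14 adjusted over the list alone; adjusted p = 0.00019, adjusted p = 0.0687 with an estimated correlation). Among them were GPNMB (2.62 ± 0.26), TGFBI (1.29 ± 0.18) and the Fc receptor gene FCGR3A (1.69 ± 0.19). Sterol genes fell (5 of 22, 8 adjusted over the list alone; adjusted p = 0.000608, adjusted p = 0.175 with an estimated correlation). MYC targets fell (12 of 20, 18 adjusted over the list alone; adjusted p = 1.4e-09, adjusted p = 0.0498 with an estimated correlation). NOLC1 was among them (−1.09 ± 0.16). Death receptors (3 of 12 rose, 5 adjusted over the list alone; adjusted p = 0.0165, adjusted p = 0.143 with an estimated correlation) and pyroptosis (6 of 13 rose, 6 adjusted over the list alone; adjusted p = 0.0317, adjusted p = 0.159 with an estimated correlation) passed, while apoptosis (adjusted p = 0.0953) and necroptosis (adjusted p = 0.373) did not. TNFRSF21 (1.43 ± 0.18), GSDME, a pore protein (1.15 ± 0.21; guide 2 alone 0.82, adjusted p = 0.086), IL18 (1.43 ± 0.29) and BMF (1.38 ± 0.15) rose. Immediate early genes passed (adjusted p = 0.0165, adjusted p = 0.314 with an estimated correlation), but were at adjusted p = 0.066 with a replicate block. The count was 656, 781 and 758 without sgNEG replicates 1, 2 and 3.

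**Figure D2:**
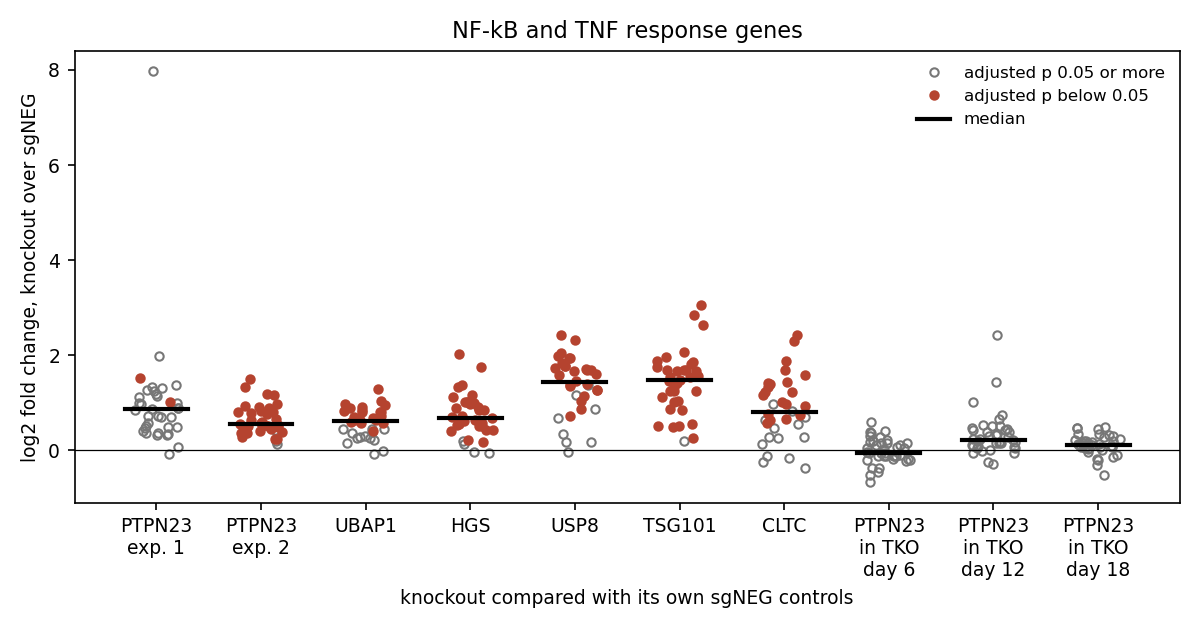
Fold changes of NF-kB and TNF response genes in each knockout against its own sgNEG libraries. The topmost point of the first PTPN23 experiment is CCL3, which had no counts in either sgNEG library, so that its height depends on the prior count.

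In order to find a common response, genes that changed in the same direction in the second PTPN23 experiment and in the UBAP1, HGS, USP8 and TSG101 knockouts were collected. DUSP1 rose in all, at 2.46, 2.38, 2.20, 3.72 and 4.48 in that order. So did ATF3 (2.46, 2.67, 2.07, 3.77 and 4.25), MET (2.57, 1.97, 2.46, 2.92 and 3.68), ADAMTS2 (2.18, 2.45, 2.51, 3.09 and 3.27), RASGEF1B, an exchange factor for small GTPases (2.39, 2.28, 2.1, 3.20 and 3.96), and GDF15 (2.06, 1.96, 2.38, 3.41 and 3.49). IL18RAP fell in all (−0.85, −0.78, −1.16, −1.59 and −1.63). So did SEPTIN1 (−1.07, −0.75, −0.82, −0.84 and −1.0), PRLR (−0.66, −0.79, −1.51, −1.43 and −1.49), APCDD1 (−0.65, −0.79, −0.93, −1.22 and −1.75), GJB6 (−0.76, −0.64, −1.01, −1.52 and −2.39) and the neuregulin gene NRG4 (−0.64, −0.81, −0.86, −1.27 and −0.94). Of 10043 genes tested in all, 512 rose and 59 fell in every knockout, against 0.988 and 0.13 for lists that were independent of each other. Independence is not given: some sgNEG libraries were alike across experiments. Chi-squared per degree of freedom was 2.5 for HGS and TSG101 replicates 2 (lowest within groups 1.99). CLTC replicate 2 and USP8 replicate 3 were at 2.12, their groups at 9.06 or more. The total of 571 was 281 at adjusted p under 0.01 and 1327 with a replicate block (957 higher, 370 lower). For UBAP1, SEPTIN1 lost its call without sgNEG replicate 2 (−0.54, adjusted p = 0.172) or 3, guide 1 replicate 2 or either guide 2 library, and GJB6 without sgNEG replicate 2 (−0.57, adjusted p = 0.068) or guide 2 replicate 2. For USP8, SEPTIN1 lost it without sgNEG replicate 2 or 3 (−0.81, adjusted p = 0.0593) and PRLR without sgNEG replicate 3 (−0.78, adjusted p = 0.209) or guide 1 replicate 1. With guide 2 alone UBAP1 lost GJB6 (−0.45, adjusted p = 0.231), PRLR (−0.64, adjusted p = 0.144) and SEPTIN1 (−0.73, adjusted p = 0.148), and USP8 lost PRLR (−1.18, adjusted p = 0.129) and SEPTIN1 (−0.80, adjusted p = 0.0515). In the CLTC knockout 398 of these genes rose and 47 fell as well (median of the 512 higher genes 0.96; camera p = 2.02e-85, p = 7e-04 with an estimated correlation), DUSP1 being at 2.31, ATF3 at 2.74 and GDF15 at 3.53.

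Across genes, log2 fold changes of these knockouts correlated with each other, from r = 0.662 (UBAP1 and CLTC) to r = 0.871 (second PTPN23 experiment and TSG101). Genes are not independent replicates, so no p-value is attached to r. In the first PTPN23 experiment the 508 higher shared genes tested had a median of 0.62 (26 changed; camera p = 2.01e-74, p = 0.0383 with an estimated correlation). CXCL8 can serve as a measure of size: its mean was 236 CPM with sgNEG in the TSG101 experiment, 1990 with guide 1 and 1070 with guide 2 (n = 3 each).

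**Figure D3:**
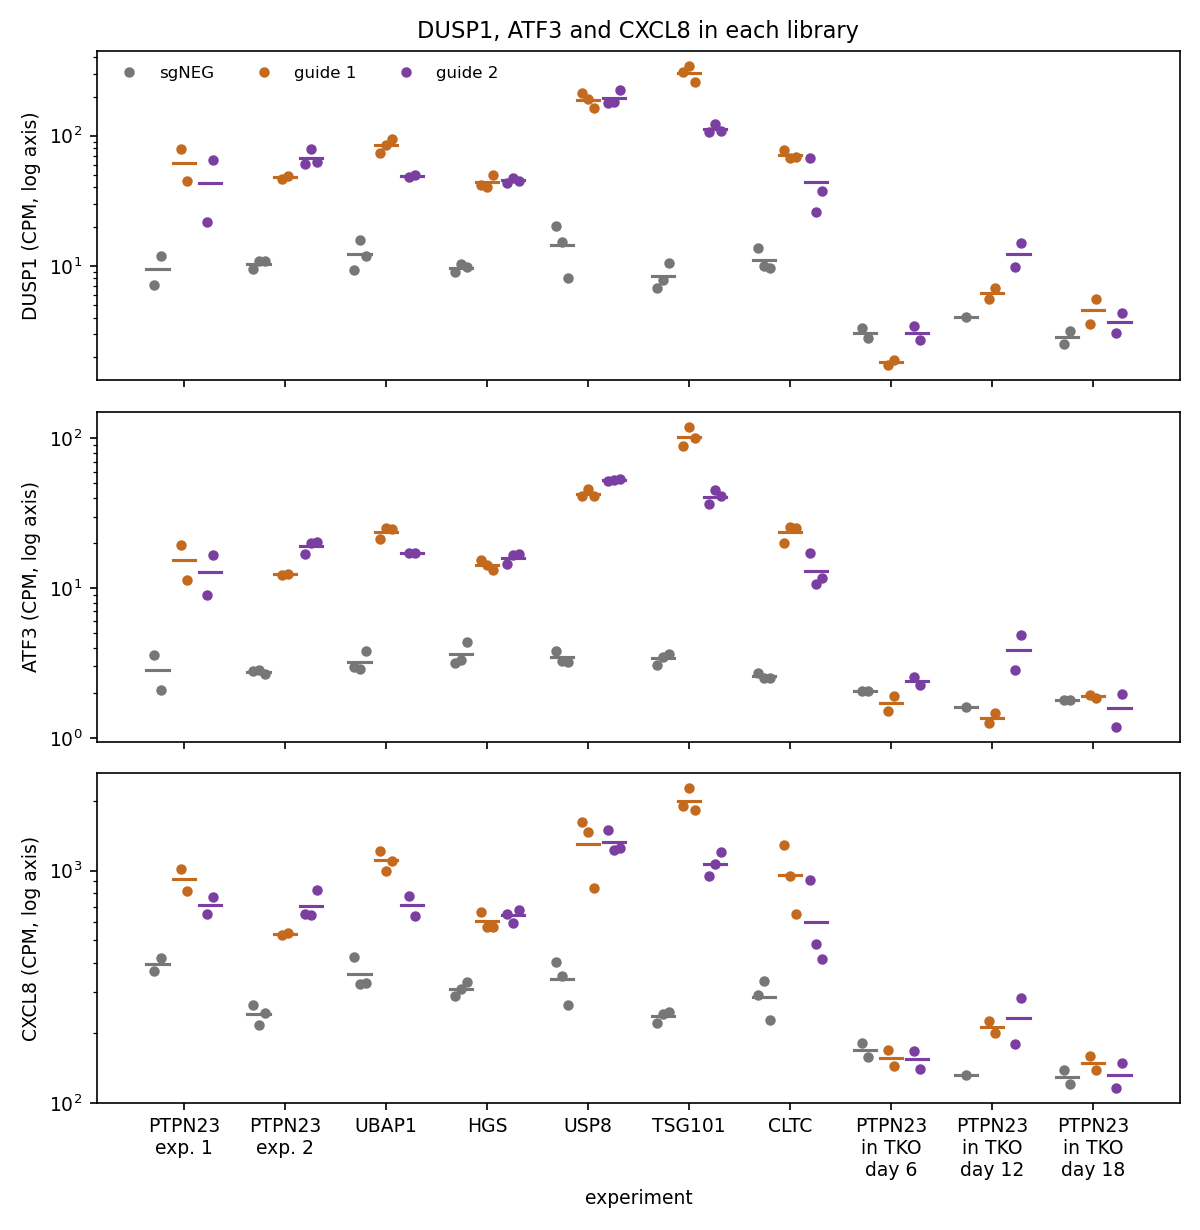
DUSP1, ATF3 and CXCL8 in every library, in CPM. Each point is 1 library.

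In order to ask whether the response to loss of PTPN23 needs CASP8, RIPK3 and GSDMD, 4 guide libraries were compared with 2 sgNEG libraries of triple-knockout cells on day 6. PTPN23 was at 54.4 and 37.8 CPM with sgNEG, 40.7 and 40.7 with guide 1 and 32 and 35.2 with guide 2 (−0.32 ± 0.17, adjusted p = 0.9). DUSP1 (−0.38 ± 0.24), ATF3 (−0.02 ± 0.25) and GDF15 (0.01 ± 0.20) were not called. CXCL8 was at 170 CPM with sgNEG and at 157 and 154 with the guides. CASP8 was at 12.7 and 17.1 CPM, RIPK3 at 5.18 and 4.19 and GSDMD at 80.1 and 59.7 in the sgNEG libraries, and none of the 3 was called with PTPN23 guides (−0.21 ± 0.19, 0.15 ± 0.19 and 0.28 ± 0.18). edgeR called 0 of 15874 genes (138 at unadjusted p under 0.05; DESeq2 1), and no gene list passed, NF-kB and TNF response being at adjusted p = 0.979, apoptosis at 0.793, death receptors at 0.592, pyroptosis at 0.979 and necroptosis at 0.238. The 490 shared higher genes tested had a median of −0.03 (interquartile range −0.18 to 0.11). Mitochondrial transcripts were highest in sgNEG replicate 2, so RNA quality may differ. The fit without guide 1 replicate 2 is left aside (below).

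On day 12 PTPN23 was at 48.3 CPM in the single sgNEG library, 42.7 and 34.7 with guide 1 and 42.3 and 30.9 with guide 2 (−0.36 ± 0.24, adjusted p = 1). CASP8 (0.20 ± 0.28), RIPK3 (−0.03 ± 0.27) and GSDMD (−0.08 ± 0.20) were not called. edgeR called 0 of 16770 genes (218 at unadjusted p under 0.05; DESeq2 2). However, NF-kB and TNF response genes passed as a list (0 of 40 changed, 0 adjusted over the list alone; median 0.22; adjusted p = 1.53e-05, adjusted p = 0.655 with an estimated correlation). The higher shared genes had a median of 0.24 (camera p = 1.33e-17, p = 0.234 with an estimated correlation). With only 1 sgNEG library these shifts cannot be told from a difference between single libraries. Fits without a guide 1 library leave that group with 1 library, without replicate 2 of another type (below), and are left aside here.

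On day 18 PTPN23 was at 40.6 and 43.4 CPM with sgNEG, 32.6 and 34.7 with guide 1 and 45 and 44.5 with guide 2 (−0.11 ± 0.11, adjusted p = 1). CASP8 (0.07 ± 0.17), RIPK3 (−0.07 ± 0.23) and GSDMD (−0.17 ± 0.11) were not called. edgeR called 0 of 15865 genes (474 at unadjusted p under 0.05; DESeq2 0). As a list NF-kB and TNF response genes passed (0 of 39 changed, 0 adjusted over the list alone; median 0.12; adjusted p = 0.000971, adjusted p = 0.599 with an estimated correlation). So did sterol genes in the lower direction (0 of 23 changed, 0 adjusted over the list alone; median −0.12; adjusted p = 0.000157, adjusted p = 0.599 with an estimated correlation). Mitochondrial transcripts, whose share follows RNA quality, moved more than these lists (0 of 13 changed, 1 adjusted over the list alone; median 0.33; adjusted p = 3.44e-07, adjusted p = 0.599 with an estimated correlation). A difference in RNA quality is thus not excluded for the list shifts of this day. The higher shared genes had a median of 0.10 (camera p = 2.1e-07, p = 0.131 with an estimated correlation). edgeR called 327 genes without guide 2 replicate 1, 45 without guide 2 replicate 2 and 3 without sgNEG replicate 2.

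The triple-knockout libraries were of 2 types: 6 of the first and 11 of the second, with r of at least 0.963 between libraries of 1 type and at most 0.79 between types. On day 6 guide 1 replicate 1 was the only library of the second type, and on day 12 guide 1 replicate 1 the only library of the first. Without guide 1 replicate 2, guide 1 on either day is this library alone. Such fits mix library type with the guide and do not measure the effect of PTPN23 loss. With all days in 1 fit and a term for library type, edgeR still called 0 of 17584 genes on days 6, 12 and 18 (908, 508 and 388 at unadjusted p under 0.05; DESeq2 without this term 1, 2 and 0). No gene was called different between the PTPN23 effects of days 18 and 6 (edgeR 0 of 17584, 452 at unadjusted p under 0.05, DESeq2 4). In simulated data edgeR recovered only 4% of 2-fold and 36% of 4-fold differences here, so a count of 0 does not show that the effects are alike. As lists, NF-kB and TNF response genes (median difference 0.16, adjusted p = 0.011, adjusted p = 0.635 with an estimated correlation) and TGF-beta targets (0.35, adjusted p = 0.011, adjusted p = 0.635 with an estimated correlation) passed.

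The effect of PTPN23 guides in triple-knockout cells on day 6 was then tested against the mean of both experiments in cells with these genes. The effect was lower for IGFBP3, which binds insulin-like growth factors (difference −2.93 ± 0.40, edgeR adjusted p = 0.00057), ID3 (−2.90 ± 0.49, adjusted p = 0.0044) and DUSP1 (−2.86 ± 0.47, adjusted p = 0.0037). The same held for SLAMF7 (−2.67 ± 0.34, adjusted p = 0.00045), LGMN (−2.56 ± 0.39, adjusted p = 0.0012), ATF3 (−2.46 ± 0.34, adjusted p = 0.00072) and GDF15 (−1.85 ± 0.24, adjusted p = 0.00045). It was higher for VAT1L (1.20 ± 0.22, adjusted p = 0.005), SEPTIN1 (1.18 ± 0.24, adjusted p = 0.0086), ACTA2, smooth muscle actin (1.34 ± 0.30, adjusted p = 0.017), HINT2, a mitochondrial hydrolase (1.14 ± 0.28, adjusted p = 0.031), and EMILIN1, an extracellular matrix protein (1.02 ± 0.22, adjusted p = 0.013). NF-kB and TNF response genes differed as a list (10 of 35 lower, 26 adjusted over the list alone; median −0.71; adjusted p = 3.97e-14, adjusted p = 0.182 with an estimated correlation). CXCL8 (−1.36 ± 0.16) and CD83 (−0.94 ± 0.16) were among them. Lysosome and autophagy genes also differed (5 of 29 lower, 13 adjusted over the list alone; adjusted p = 7.02e-07, adjusted p = 0.159 with an estimated correlation), and so did TGF-beta targets (5 of 11 lower, 7 adjusted over the list alone; adjusted p = 1.81e-05, adjusted p = 0.159 with an estimated correlation). The apoptosis (adjusted p = 0.191), death receptor (adjusted p = 0.149), pyroptosis (adjusted p = 0.146) and necroptosis (adjusted p = 0.917) lists did not pass, although BMF (−1.11 ± 0.16), CFLAR (−0.68 ± 0.13) and CYLD (−0.76 ± 0.13) did. In all 417 of 11190 genes differed (50 higher, 367 lower), 105 against the first experiment alone and 714 with DESeq2. Fewer genes differed without replicate 3, which leaves 1 library in guide 1 of the second experiment, and more without replicate 1 or 2. Without replicate 1 or 2 all triple-knockout groups and all groups of the first experiment hold 1 library. The spread then comes from the second experiment alone, so the higher counts do not measure how robust the difference is. ACTA2, HINT2, EMILIN1 and CFLAR lost their call without replicate 3. HINT2 also lost it without replicate 1 (0.53) and in edgeR with a replicate block (1.11, adjusted p = 0.0523). ACTA2, SEPTIN1, HINT2, EMILIN1, CFLAR and ID3 lost it against the first experiment alone.

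In order to compare the knockouts with each other, the effect of each was tested against the effect in the second PTPN23 experiment, each measured against its own sgNEG libraries. Knockout and experiment cannot be separated in these tests. UBAP1 and PTPN23 differed in 0 of 11023 genes with edgeR (457 at unadjusted p under 0.05, DESeq2 11, 36 with a replicate block). In simulated data edgeR recovered 34% of 1.5-fold and 84% of 2-fold differences here. Sterol genes differed as a list (median −0.25, camera adjusted p = 1.77e-08, adjusted p = 0.00925 with an estimated correlation), and 5 lists passed in all, or 8 with a replicate block.

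For HGS against PTPN23, OLFML2B, an extracellular matrix protein (1.00 ± 0.13, edgeR adjusted p = 0.00017), and PTPN23 itself (1.00 ± 0.13, adjusted p = 0.00014) were higher, with S100B (1.29 ± 0.27, adjusted p = 0.019), the calcium channel subunit gene CACNA2D3 (1.26 ± 0.21, adjusted p = 0.0022) and TMEM150B (1.02 ± 0.22, adjusted p = 0.019). FLT1, a VEGF receptor (−1.55 ± 0.25, adjusted p = 0.0022), GZMA (−1.10 ± 0.19, adjusted p = 0.004), SNAI1 (−1.09 ± 0.24, adjusted p = 0.025), HEG1 (−1.02 ± 0.18, adjusted p = 0.0054) and GABRR2 (−1.01 ± 0.22, adjusted p = 0.022) were lower. Heat shock genes were lower as a list (3 of 10, 6 adjusted over the list alone; camera adjusted p = 2.94e-06, adjusted p = 0.0593 with an estimated correlation). HSPD1 was among them (−0.43 ± 0.09). Sterol genes were lower as well (4 of 23, 14 adjusted over the list alone; adjusted p = 1.54e-06, adjusted p = 0.267 with an estimated correlation). HMGCS1 was among them (−0.69 ± 0.13). Monocyte maturation genes were higher (3 of 28, 10 adjusted over the list alone; adjusted p = 0.000115, adjusted p = 0.0869 with an estimated correlation). MMP9 was among them (0.92 ± 0.12). In all 139 of 11310 genes differed (94 higher, 45 lower), 235 with DESeq2 and 582 with a replicate block, although the numbers pair only the PTPN23 libraries here. Without replicates 1, 2 and 3 the count was 41, 11 and 10, and all genes named here except OLFML2B, PTPN23 and MMP9 lost their call in at least 1 of these (adjusted p from 0.0556 to 0.474), all in the same direction as before (SNAI1 at −0.92, −1.25 and −1.08).

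For USP8 against PTPN23, ATF3 (1.29 ± 0.19, edgeR adjusted p = 0.0051), SLAMF7 (1.68 ± 0.23, adjusted p = 0.0032), ADA, adenosine deaminase (1.65 ± 0.32, adjusted p = 0.028), MRNIP, a DNA repair factor (1.67 ± 0.36, adjusted p = 0.038), IL1R2 (1.87 ± 0.45, adjusted p = 0.048) and APOE (1.96 ± 0.45, adjusted p = 0.043) were higher. HHLA2 (−1.24 ± 0.21, adjusted p = 0.011), the transporter gene SLCO4C1 (−1.23 ± 0.30, adjusted p = 0.048), HSPA4L, a chaperone (−1.17 ± 0.25, adjusted p = 0.038), ERLIN1 (−1.04 ± 0.22, adjusted p = 0.038) and POGLUT3 (−1.0 ± 0.22, adjusted p = 0.039) were lower. NF-kB and TNF response genes were higher as a list (9 of 34, 15 adjusted over the list alone; camera adjusted p = 1.64e-11, adjusted p = 0.144 with an estimated correlation). ICAM1 was among them (0.78 ± 0.14). Immediate early genes were higher too (5 of 19, 11 adjusted over the list alone; adjusted p = 4.22e-07, adjusted p = 0.144 with an estimated correlation). In all 176 of 10076 genes differed (131 higher, 45 lower), 549 with DESeq2, 902 with a replicate block (as for HGS) and 84 without the shallowest USP8 guide 1 library. All genes named here lost their call without replicate 1 (adjusted p from 0.506 to 0.712) and without replicate 2 (from 0.128 to 0.213), and HSPA4L, SLCO4C1 and ICAM1 also without replicate 3 (0.116, 0.0711 and 0.0532). All kept their direction, ATF3 being at 1.33 and 1.28 without replicates 1 and 2.

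TSG101 loss had the larger effects when tested against PTPN23. DUSP1 (2.02 ± 0.21, edgeR adjusted p = 5.2e-06), ATF3 (1.79 ± 0.26, adjusted p = 0.00014), SNAI1 (1.77 ± 0.32, adjusted p = 0.0011), the cytokine gene IL23A (2.36 ± 0.48, adjusted p = 0.0053) and the chemokine gene CCL20 (1.86 ± 0.38, adjusted p = 0.0051) were higher. GJB6 (−1.64 ± 0.22, adjusted p = 7.7e-05), the chemokine receptor gene CCR2 (−1.35 ± 0.15, adjusted p = 1.2e-05), F13A1 (−1.30 ± 0.19, adjusted p = 0.00018), TSG101 itself (−1.18 ± 0.12, adjusted p = 3.8e-06) and ART3 (−1.15 ± 0.18, adjusted p = 0.00034) were lower. NF-kB and TNF response genes were higher as a list (22 of 35, 28 adjusted over the list alone; camera adjusted p = 1.44e-20, adjusted p = 0.0316 with an estimated correlation). CXCL8 was among them (1.29 ± 0.15). Immediate early genes were higher too (12 of 21, 15 adjusted over the list alone; adjusted p = 4.81e-14, adjusted p = 0.0316 with an estimated correlation). Ferroptosis and NRF2 targets were higher as well (10 of 18, 16 adjusted over the list alone; adjusted p = 3.04e-13, adjusted p = 0.0168 with an estimated correlation), SLC7A11 by 1.24 ± 0.19. TGF-beta targets were higher (7 of 11, 8 adjusted over the list alone; adjusted p = 2.94e-08, adjusted p = 0.00421 with an estimated correlation). Granulocyte and progenitor genes were lower (4 of 10, 6 adjusted over the list alone; adjusted p = 6.49e-05, adjusted p = 0.0724 with an estimated correlation). MPO was among them (−0.92 ± 0.15). In all 676 of 11069 genes differed (524 higher, 152 lower). The count was 48, 604 and 218 without replicates 1, 2 and 3. IL23A, CCL20, SNAI1, F13A1, ART3 and SLC7A11 lost their call without replicate 1 (adjusted p from 0.0591 to 0.136), and IL23A also without replicate 2 (adjusted p = 0.157), where it was at 1.97.

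For CLTC against PTPN23, CLDN1 (2.32 ± 0.40, edgeR adjusted p = 0.012), MSR1 (2.12 ± 0.42, adjusted p = 0.028), TNFAIP8L3 (1.85 ± 0.28, adjusted p = 0.0061), the adhesion gene JAML (1.56 ± 0.28, adjusted p = 0.017) and FFAR2, a receptor for short fatty acids (1.31 ± 0.26, adjusted p = 0.027), were higher. MPO (−2.19 ± 0.28, adjusted p = 0.002), SNAI1 (−1.77 ± 0.29, adjusted p = 0.0074), the granulocyte adhesion gene CEACAM6 (−1.60 ± 0.29, adjusted p = 0.02), GLT1D1 (−1.57 ± 0.21, adjusted p = 0.0023) and THBS1, thrombospondin (−1.55 ± 0.24, adjusted p = 0.0058), were lower. Sterol genes were lower as a list (1 of 22, 14 adjusted over the list alone; median −0.58; camera adjusted p = 4.51e-11, adjusted p = 0.0195 with an estimated correlation). Monocyte maturation genes were higher (2 of 27, 7 adjusted over the list alone; adjusted p = 0.00218, adjusted p = 0.0426 with an estimated correlation). FCGR3A was among them (0.98 ± 0.20). NF-kB and TNF response genes did not pass as a list (adjusted p = 0.0715). In all 50 of 10615 genes differed (26 higher, 24 lower), 166 with DESeq2 and 315 with a replicate block. All genes named here lost their call when replicate 1, 2 or 3 was left out (adjusted p from 0.0668 to 0.65), as did all 50 genes. Their differences kept their direction: without replicates 1, 2 and 3 CLDN1 was at 2.54, 2.38 and 2.06, FFAR2 at 1.0, 1.6 and 1.41 and GLT1D1 at −1.32, −1.66 and −1.66.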

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

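All tests in this part were chosen only after the result was seen, except those of a less complete loss of PTPN23, of a batch and of overlapping genes on the opposite strand. Tests of a difference between effects found 417 genes for PTPN23 in triple-knockout cells on day 6 against wild-type cells, and, against the second PTPN23 experiment, 139 genes for HGS, 176 for USP8, 676 for TSG101 and 50 for CLTC. No group holds 4 or more libraries, so single extreme libraries were not searched for.

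For PTPN23 guides edgeR called 29 and 3511 genes in both wild-type experiments and 0 in triple-knockout cells on day 6 (DESeq2 1). On that day edgeR recovered only 34% of simulated 2-fold changes. Without the day 6 library of the other type 324 genes differed, so that library does not explain the difference. Genes higher in all ESCRT-pathway knockouts had a median of −0.026 there (interquartile range −0.183 to 0.107). It was 0.616 (0.416 to 0.913) in the first wild-type experiment. Ranges span genes, so library spread hiding the same change is not excluded. A less complete loss of PTPN23 goes with the data. PTPN23 RNA fell less in triple-knockout cells by 0.37 (SE 0.17), past the planned limit of 2 SE, though edgeR did not call this difference (adjusted p = 0.22). RNA does not measure the protein, so this explanation stays open. A need for CASP8, RIPK3 or GSDMD could also explain the missing response, but cell type and experiment are the same split, so these cannot be told apart.

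Among the triple-knockout libraries, guide 1 replicate 1 of day 6 (mean r 0.786 with its day, 0.973 with its type) and guide 1 replicate 1 of day 12 (0.773 and 0.978) resemble libraries of another day. Swapped days are argued against, because in 7 of the 10 gene lists that separate the days both libraries lie on the side of their own day, and in 0 on the other side. A batch of library preparation or counting stays open. The difference between both guide 1 replicates on day 6 and the reversed difference on day 12 correlate across genes with r = 0.966, but each pair holds 1 library of either type, so this restates the types and tests no cause. Of the genes at least 4-fold apart in both, 97.6% overlap a gene on the opposite strand, against 56.7% of other genes (Fisher p = 2.5e-222), so how reads of overlapping genes were counted may differ between the types. No biological explanation was tested.

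Sterol genes moved apart between knockouts. A shift of all genes by scaling is argued against for CLTC against PTPN23. The list lay at −0.582 (interquartile range −0.693 to −0.462) and all other genes at −0.003 (−0.2 to 0.219), a difference of −0.579 that a common shift leaves at 0. This is no independent test, since the list was flagged by camera, which already sets it against the other genes. A difference between experiments goes with the data: the same knockout differed by −0.432 between both PTPN23 experiments. The differences between knockouts in this list may therefore come from culture or handling, and an effect of the knockouts stays open.

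Other splits of the same libraries were fitted to ask whether chance can be excluded. Chance is argued against for the second PTPN23 experiment (real 3511, highest other 3689, 2 of 100 splits as large), HGS (4932, 5131, 2 of 100), USP8 (2693, 3053, 3 of 100) and TSG101 (5206, 4229, 1 of 100). In the first 3 of these the other splits as large keep the real sgNEG libraries and only mix the guides. For UBAP1 (817, 1367, 3 of 100) and CLTC (1463, 2516, 2 of 100) few splits were as large too, but chance is not excluded. The highest other split there mixes controls and gives more genes than the real one. For UBAP1 it takes sgNEG replicates 2 and 3 with guide 1 replicate 3 as controls, and for CLTC guide 1 replicates 1 and 3 with guide 2 replicate 1. No other split used the block (real 2689 and 2911). Among splits within replicate numbers, 2 of 72 were as large for the second PTPN23 experiment (highest other 4505) and for UBAP1 (846), with the real controls kept, and 1 of 100 for CLTC (1428).

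For differences between effects, libraries of 1 experiment that share a replicate number were kept together, since the numbers pair the libraries of the second PTPN23 experiment. Such splits are too few for a share under 0.05: 10 each for HGS (real 139, highest other 0), USP8 (176, 0), TSG101 (676, 0) and CLTC (50, 0), of which 1 was as large. In 50 splits that part these sets the highest other was 354, 528, 235 and 79 in the same order. For UBAP1 the real count was 0, so all 6 splits were as large by construction and this decides nothing. Among 50 splits that part the sets, 2 gave 2198 and 2400 genes, which points to a structure of these libraries. Both part sgNEG replicates 2 and 3 of UBAP1 and 2 of PTPN23 from the other sgNEG libraries, as did splits with 0 genes. The cause was not tested.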

How the results depend on the processing

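The fits without the shallowest USP8 library and with a library type term, and the leave-out of libraries of another type, were chosen only after results were seen; the other alternatives were planned. Why a setting moved a result was not tested. The labels define no pairing, and p-values measure only the spread between these libraries.

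Guide 1 alone gave 1 gene in the first PTPN23 experiment and 1231 in the second; guide 2 alone 2 in the first, 367 for UBAP1 and 351 for CLTC. Without the filter the first PTPN23 experiment gave 356 genes, triple-knockout day 12 gave 1 and day 18 gave 11. With a replicate block counts were 1 (first PTPN23 experiment, LIPG, the other genes named there being at adjusted p from 0.0749 to 0.0898), 2689 (UBAP1) and 2911 (CLTC), for differences from PTPN23 36 (UBAP1), 582 (HGS), 902 (USP8) and 315 (CLTC), and 1327 for shared genes; 8 lists differed for UBAP1. Beyond these the block ended the camera calls of death receptors (first PTPN23 experiment), pyroptosis (HGS), immediate early genes (CLTC) and, for triple-knockout against wild-type, immediate early, glycolysis and ribosomal protein genes. Libraries closest to their own number were 7 of 9 for HGS, 7 of 9 for TSG101, 5 of 9 for USP8, 6 of 6 on triple-knockout day 18 and 4 of 6 in the first PTPN23 experiment.

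DESeq2 called 310 genes (first PTPN23 experiment), 1 and 2 (triple-knockout days 6 and 12), 714 (triple-knockout against wild-type), 3 (second against first PTPN23 experiment), 4 (day 18 against 6) and, against PTPN23, 11 (UBAP1), 235 (HGS), 549 (USP8) and 166 (CLTC). Against the first wild-type experiment alone 105 genes differed. Shared genes at adjusted p below 0.01 numbered 281. Without the shallowest USP8 library 84 genes differed from PTPN23.

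With an estimated correlation the camera lists passing went from 13 to 0 (first PTPN23 experiment), 15 to 0 (second), 14 to 6 (UBAP1), 22 to 5 (HGS), 11 to 0 (USP8), 15 to 2 (TSG101), 14 to 1 (CLTC), 4 to 0 and 8 to 0 (triple-knockout days 12 and 18), 13 to 0 (against wild-type), 6 to 0 (between PTPN23 experiments), 5 to 0 (day 18 against 6), 5 to 1 (UBAP1 against PTPN23), 8 to 0 (HGS), 7 to 0 (USP8) and 13 to 2 (CLTC). With fry, which asks whether a list changes at all, 0, 25, 21 and 29 lists passed for the first and second PTPN23 experiment, USP8 and TSG101, 0 on triple-knockout days 12 and 18, 0 between PTPN23 experiments, 0 for day 18 against 6, and 1 and 6 for UBAP1 and CLTC against PTPN23.

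Correlations at a mean log2 CPM of at least 4 rose to 0.875 (PTPN23 and UBAP1), 0.814 (PTPN23 and HGS), 0.9 (PTPN23 and TSG101), 0.827, 0.708, 0.862 and 0.696 (UBAP1 with HGS, USP8, TSG101 and CLTC), 0.807, 0.856 and 0.81 (HGS with USP8, TSG101 and CLTC), 0.869 and 0.842 (USP8 with TSG101 and CLTC) and 0.799 (TSG101 and CLTC).

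Leaving out 1 library gave 0 to 307 genes for the first PTPN23 experiment, 2367 to 4200 for the second, 383 to 2860 for UBAP1, 3985 to 5457 for HGS, 1628 to 3133 for USP8, 4137 to 6226 for TSG101, 656 to 1603 for CLTC, and 0 to 62, 0 to 2018 and 0 to 327 for triple-knockout days 6, 12 and 18. Leaving out 1 replicate number gave 120 to 2153 for triple-knockout against wild-type, 0 to 3 between PTPN23 experiments, 10 to 41 (HGS), 0 to 174 (USP8), 48 to 604 (TSG101) and 0 to 0 (CLTC) against PTPN23. For day 18 against 6 these fits had no residual degrees of freedom, and day 12 has no fit without its only sgNEG library. These were not run. The highest counts on triple-knockout days 6 and 12 came without guide 1 replicate 2, which leaves guide 1 as 1 library of another type. That for triple-knockout against wild-type came without replicate 2, which leaves 1 library in each triple-knockout group.

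Of values printed in the report, those that changed sign, none of them called, were UBAP1 with UBAP1 guide 1 alone (−0.219), on triple-knockout day 12 RIPK3 and GSDMD with guide 1 alone (0.0871 and 0.0249), and on day 18 PTPN23 with guide 2 alone (0.0915) and RIPK3 with guide 1 alone (0.0284). Leaving out 1 library moved CASP8 on day 6 from −0.405 to 0.0282 (without sgNEG replicates 1 and 2). On day 12 it moved RIPK3 from −0.133 to 0.0588 (without guide 1 replicates 1 and 2) and GSDMD from −0.172 to 0.014 (without guide 2 replicates 1 and 2). On day 18 it moved CASP8 from −0.0434 (without sgNEG replicate 2; −0.000354 without guide 1 replicate 1) to 0.205 and RIPK3 from −0.363 to 0.308 (without sgNEG replicates 2 and 1). Of 281 fold changes called in the report, calls were kept in 1138 of 1156 values with another tool, size factor, filter, block or experiment, 396 of 432 with 1 guide alone and 1891 of 2032 with a library left out, and no called value changed sign. These shares are in part fixed by choice, since genes were named for moving the same way with both guides and, in lists, for keeping their call without single libraries, so they do not measure how stable other calls are. RLE size factors, the library type term and the second wild-type experiment alone moved 0 counts of genes or lists by over 1.5 times.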

Other observations

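The tests of this part were planned, except those on the genes shared by the ESCRT-pathway knockouts in other experiments, which were chosen after the shared genes were known.

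ESCRT machinery genes did not pass camera, which compares a list with the other genes, in any wild-type knockout: adjusted p was 0.666 and 0.949 in the first and second PTPN23 experiment, 0.639 for UBAP1, 0.509 for HGS, 0.154 for USP8, 0.373 for TSG101 and 0.342 for CLTC. With fry, which asks whether a list changes at all, they passed for HGS (adjusted p = 0.00144), USP8 (adjusted p = 0.0167) and TSG101 (adjusted p = 0.0213). Single members moved, with 13 rising and 5 falling in the TSG101 knockout. Clathrin-mediated endocytosis genes (adjusted p = 0.176, 0.0669, 0.639, 0.12, 0.175, 0.136 and 0.707 in the same order), p53 targets (0.316, 0.225, 0.639, 0.183, 0.228, 0.373 and 0.156) and iron genes (0.176, 0.0914, 0.639, 0.125, 0.991, 0.577 and 0.707) did not pass camera either, nor did fatty acid and LXR genes (0.154, 0.167, 0.878, 0.525, 0.295, 0.712 and 0.342). With fry all of these lists passed in the second PTPN23 experiment and for TSG101, all but fatty acid and LXR genes for HGS, clathrin and p53 genes for USP8, and p53 targets for CLTC (adjusted p = 0.0135).

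JAK-STAT feedback genes rose in the second PTPN23 experiment (7 of 14, 9 adjusted over the list alone; adjusted p = 0.000317, adjusted p = 0.105 with an estimated correlation), for example SOCS3 (1.91 ± 0.13). ERK output genes rose as well (8 of 12, 9 adjusted over the list alone; adjusted p = 0.0036, adjusted p = 0.231 with an estimated correlation), led by DUSP4 (1.66 ± 0.11), as did glycolysis and hypoxia genes (12 of 24, 12 adjusted over the list alone; adjusted p = 0.000737, adjusted p = 0.231 with an estimated correlation). Cytosolic ribosomal protein genes fell there (23 of 23, 23 adjusted over the list alone; adjusted p = 1.41e-08, adjusted p = 0.244 with an estimated correlation), and oxidative phosphorylation genes fell (7 of 20, 7 adjusted over the list alone; adjusted p = 0.00392, adjusted p = 0.414 with an estimated correlation). In the HGS knockout ER stress genes rose (14 of 23, 14 adjusted over the list alone; adjusted p = 0.00786, adjusted p = 0.188 with an estimated correlation), for example DDIT4 (1.11 ± 0.07), as did adhesion genes (10 of 20, 10 adjusted over the list alone; adjusted p = 0.0259, adjusted p = 0.385 with an estimated correlation), and MLL fusion programme genes fell (6 of 15, 6 adjusted over the list alone; adjusted p = 0.0125, adjusted p = 0.132 with an estimated correlation), for example HOXA9 (−0.46 ± 0.06).

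Of markers of other cell types few were expressed. Lymphoid markers did not pass camera in the first PTPN23 experiment (4 tested, adjusted p = 0.418), and epithelial and fibroblast markers did not in the second (adjusted p = 0.927) or in the HGS knockout (adjusted p = 0.472). Fewer than 3 erythroid and megakaryocytic markers were tested in each wild-type table. Replication histone genes, which mark RNA without poly(A) tails, did not pass in the HGS (adjusted p = 0.298) or USP8 knockout (adjusted p = 0.142).

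Mitochondrial transcripts, tested only in triple-knockout cells, had a median of −0.43 on day 6 (adjusted p = 0.128), 0.07 on day 12 (adjusted p = 0.491) and 0.33 on day 18 (0 of 13 changed, 1 adjusted over the list alone; adjusted p = 3.44e-07, adjusted p = 0.599 with an estimated correlation). Their share of a library also follows RNA quality.

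The genes that fell in all ESCRT-pathway knockouts had a median of −0.42 in the first PTPN23 experiment, −0.88 in the CLTC knockout, 0.08 on triple-knockout day 6, −0.15 on day 12 and −0.08 on day 18.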
